A study of Homo sapiens with 20 samples.

How the data were processed

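The series holds 20 RNA-seq libraries of cells labelled MHCC-97H, a human hepatocellular carcinoma line, in 4 groups of 5. The identity of the line was not tested here. Per the labels' protocols, total RNA was taken with TRIzol, polyA RNA was measured, and libraries were made with a VAHTS Universal kit (V6). Per the submitters' processing notes, fastp, HISAT2 and HTSeq were used with the human build hg38; versions, their order, the annotation and the strand setting are not given in the sources used here. The authors deposited one table of counts per gene symbol and one table of FPKM for the same 26038 symbols and 20 samples. The deposited counts are whole numbers that were not normalised. The deposited FPKM values equal the count divided by gene length and by the library's total count, with 1 length per gene, so they carry the library-size scaling alone. Every listed gene had at least 1 count in some library. None of the 13 mitochondrially encoded genes of a fixed list was in the table, and that list was not analysed here.

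Depth was 32219900 to 39689900 counts per library, to 6 digits, and 18105 to 20480 genes had at least 1 count. Samples were grouped by their titles, and each column was matched to its sample by title. No 2 libraries of a group held identical counts. Nothing says that the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Sampling intervals and floors cover counting error only.

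The computation started from the deposited counts. Each comparison used only its 2 groups: R-47 against R-37, NFS1 against NC, and NC against R-47. Genes were kept by edgeR's filterByExpr with its default minimum count of 10 and total of 15, libraries were scaled by TMM, and edgeR's quasi-likelihood test (glmQLFit, glmQLFTest) was used with Benjamini-Hochberg adjustment at 0.05. SE values are the log2 fold change divided by the square root of the F statistic. Levels are CPM from edgeR's cpm function, scaled by TMM within the comparison, as mean ± SD over the 5 libraries of a group. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used, with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 for tables and plots.

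The test, the groups compared, 35 gene lists and the rule for naming genes were fixed before the data were examined. Each list with at least 5 tested members was tested with limma's camera on voom values, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 34 lists. Camera with an estimated correlation and fry were alternatives. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. Genes called after heating were tested as sets in the knockdown comparison by camera with an estimated correlation.

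Named genes were NFS1, GPX4, SLC7A11, ACSL4, AIFM2, TFRC, FTH1, LDHA, CDH1 and VIM in the heat and knockdown comparisons. To these were added the 5 highest and 5 lowest log2 fold changes (3 and 3 for NC against R-47) among called genes of average log2 CPM of at least 2 whose groups did not overlap, leaving out unnamed or noncoding-style symbols. For each list past the set test, the 2 called members of smallest adjusted p in the direction of the list were added, 1 of which is not reported here. Last came the 4 genes raised by heating and lowered in the knockdown, and the 4 with the reverse, of largest smaller change. Other genes named as examples of a list were chosen after their values were seen.

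Gene positions came from the RefSeq annotation of GRCh38, which matched 94.9% of the symbols. GC content came from GENCODE transcripts and was known for 90.4 to 92.7% of the tested genes, and gene length from the ratio of counts to FPKM. The count test was checked on simulated counts with 200 changed genes of known fold. In the heat design it recovered 54% of genes changed 1.25-fold, 80% at 1.5-fold, 98% at 2-fold and 100% at 4-fold. In the knockdown design the shares were 28, 70, 100 and 100%, and in the NC against R-47 design 66, 94, 100 and 100%.

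Alternatives were DESeq2 size factors in edgeR, library size alone, no filter, a minimum count of 50, DESeq2, limma-voom, all 20 libraries in one fit, the replicate number as a block, and each library left out. Further ones were limma on log2(FPKM + 1) or log2(FPKM + 0.1) with a mean FPKM of at least 1, or with no filter. Settings added after seeing the data were length and GC offsets, leaving out genes of chromosome 10 and Xq, and leaving out pairs of libraries that stood apart. Reads of near-identical copies can be split between genes in a count table, so HSPA1A, HSPA1B and HSPA6, the AKR1C family, CSAG3 and histone genes are uncertain. PolyA RNA was measured, so the values of histone genes need not stand for all of their transcript. Antisense and overlapping genes cannot be separated without a stated strand setting.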

Results

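The study asked how sublethal heat, as at the edge of an insufficient microwave ablation, changes liver cancer cells, with histone lactylation, ferroptosis resistance and metastasis as its themes. Cells labelled MHCC-97H, a human hepatocellular carcinoma line, were held in a water bath for 15 minutes and returned to an incubator for 24 hours. In the first experiment wild-type cells were held at 37 °C (R-37) or 47 °C (R-47). In the second, cells labelled wild-type (NC) and cells labelled as NFS1 knockdown by shRNA (NFS1) were all held at 47 °C. Each group had 5 RNA-seq libraries. Total counts per library, to 6 digits, were 32219900 to 39689900 in R-37 and 35431100 to 39094000 in R-47. They were 35732500 to 36744100 in NC and 35426500 to 36253400 in NFS1.

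The first comparison asked what 47 °C left behind in wild-type cells 24 hours later. Most heat shock chaperones were lower in R-47 than in R-37, together with chaperones of the endoplasmic reticulum, iron-handling genes, NRF2 targets and cholesterol synthesis genes. HSP90AA1, a cytosolic chaperone, fell from 1734 ± 131 to 820 ± 51 CPM (SD, n = 5 each), and the inducible HSP70 gene HSPA1A from 171 ± 32 to 72.1 ± 9.2 CPM. The small heat shock protein CRYAB moved the other way, from 0.844 ± 0.137 to 15.7 ± 2.1 CPM, the highest rise among the genes named by rule. Interferon-stimulated genes were higher, and so were histone genes, whose list did not pass with an estimated correlation (adjusted p = 0.056). Of 14344 genes tested, 1714 were higher and 1890 lower by edgeR's quasi-likelihood test, and 314 of these changed more than 2-fold. Scaled by library size alone, 2977 rose and 1013 fell, so the balance between rises and falls depended on the scaling.

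Of 24 heat shock chaperones, 21 fell and 1, CRYAB, rose (log2 fold change 4.22, SE 0.13, adjusted p = 1.46e-11, edgeR). The count adjusted over the list alone was also 21 and 1. HSP90AA1 fell by 1.08 on the log2 scale and HSP90AB1 by 0.61, HSPH1 by 1.06 and HSPA8 by 0.80. HSPA1A fell by 1.24 and HSPA1B by 0.89, both uncertain because the copies are near-identical, and with all 20 libraries in one fit neither call held, at falls of nearly the same size (log2 fold change -1.25 and -0.90, adjusted p = 0.054 and 0.18). The list lay below the other genes by camera (adjusted p = 8.37e-17, and adjusted p = 0.0096 with an estimated correlation). Of 24 genes of the endoplasmic reticulum unfolded protein response, 19 fell and none rose (20 and none adjusted over the list alone; camera adjusted p = 9.88e-16, adjusted p = 0.0039 with an estimated correlation). HSP90B1, a chaperone of that compartment, fell from 1292 ± 77 to 741 ± 44 CPM, and the disulfide isomerase PDIA4 from 406 ± 12 to 252 ± 10 CPM.

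**Figure D1:**
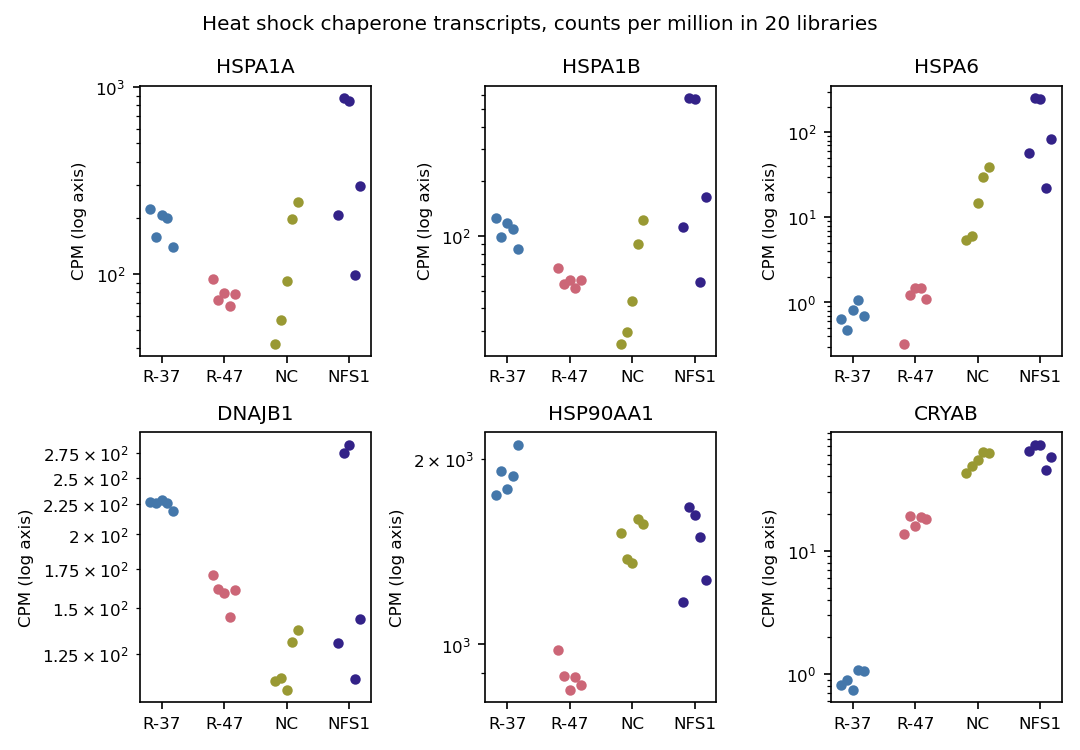
CPM on a log axis for 6 heat shock chaperones, 1 point per library in each of the 4 groups, scaled over all 20 libraries. HSPA1A averages 186 CPM in R-37, 78.3 in R-47, 126 in NC and 463 in NFS1, with a wide spread in the last 2 groups.

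Iron genes fell as a group. Of 23 genes of iron uptake, storage and export, 11 fell and none rose, with the same numbers adjusted over the list alone (camera adjusted p = 0.000467, adjusted p = 0.031 with an estimated correlation). TF, the plasma iron carrier, fell by 1.21 on the log2 scale (SE 0.09), CP, a ferroxidase, by 0.74 (SE 0.07), and TFRC, the transferrin receptor, from 795 ± 52 to 585 ± 37 CPM (log2 fold change -0.44, SE 0.05, adjusted p = 2.82e-05, edgeR). FTH1, the ferritin heavy chain, fell by 0.23 (SE 0.06), a call that ended when library size alone was the scaling (adjusted p = 0.056) and in the FPKM settings (0.0996 to 0.35). Of 25 NRF2 targets, 13 fell and 2 rose (16 and 3 adjusted over the list alone; camera adjusted p = 0.000374, adjusted p = 0.034 with an estimated correlation). Among them the aldo-keto reductases AKR1B10 and AKR1C2 fell by 0.53 and 0.36. With library size alone 4 iron genes fell and none rose, and of the NRF2 targets 4 rose and 5 fell.

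The ferroptosis lists did not pass the set test. Of 26 ferroptosis suppressors, 6 fell and 2 rose, and these numbers held adjusted over the list alone (camera adjusted p = 0.16). Of 25 drivers, 7 fell and 4 rose (8 and 6 adjusted over the list alone; camera adjusted p = 0.41). AIFM2, a CoQ oxidoreductase that limits lipid peroxidation, rose from 54.7 ± 5.0 to 63.8 ± 1.6 CPM (log2 fold change 0.22, SE 0.06, adjusted p = 0.016, edgeR). GPX4, the lipid hydroperoxide reductase, had a log2 fold change of 0.15 (SE 0.06, adjusted p = 0.079). The cystine transporter gene SLC7A11 was at 294 ± 37 and 302 ± 24 CPM and ACSL4 at 82.5 ± 10.3 and 76.6 ± 5.3 CPM, neither past the threshold. NFS1, the cysteine desulfurase of iron-sulfur cluster assembly, was at 82.2 ± 3.4 and 84.7 ± 5.0 CPM and did not pass either. Of 27 iron-sulfur cluster assembly genes, 4 fell and 3 rose (4 and 3 adjusted over the list alone; camera adjusted p = 0.52). GPX4 passed as higher without R-37 replicate 1 (adjusted p = 0.010), with library size alone (adjusted p = 0.0079; 0.0079 to 0.49 over all alternatives) and in the 3 FPKM settings (0.010 to 0.031). Library size alone also turned the balance of suppressors to 6 up and 4 down, of drivers to 7 up and 4 down and of iron-sulfur genes to 8 up and 2 down. Leaving out R-37 replicate 1 or R-47 replicate 1 turned the sign of SLC7A11, to -0.02 and -0.00089. With length and GC offsets, chosen after seeing the data, SLC7A11 passed as higher (log2 fold change 0.18, adjusted p = 6.76e-05) and GPX4 was at -0.04.

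Of the lipid, energy and ribosomal lists, only cholesterol synthesis passed camera with an estimated correlation as well. Of 24 cholesterol synthesis genes, 13 fell and 1 rose (15 and 1 adjusted over the list alone; camera adjusted p = 0.000389, adjusted p = 0.032 with an estimated correlation), among them INSIG1 by 0.58 on the log2 scale. Of 19 fatty acid synthesis genes, 7 fell and 2 rose (8 and 4 adjusted over the list alone; camera adjusted p = 0.021, adjusted p = 0.19 with an estimated correlation). The stearoyl-CoA desaturase SCD fell from 592 ± 19 to 346 ± 15 CPM and ACACA by 0.39. In the TCA cycle 5 of 28 genes fell, with 5 adjusted over the list alone (camera adjusted p = 0.021, adjusted p = 0.063 with an estimated correlation), including SUCLG2 by 0.47 and CS by 0.19. Of 52 ribosomal protein genes 14 fell, likewise 14 adjusted over the list alone (camera adjusted p = 0.000374, adjusted p = 0.62 with an estimated correlation), RPL6 by 0.25 and RPS24 by 0.23. Of 25 genes of glycolysis and lactate, 6 fell and 3 rose (7 and 5 adjusted over the list alone; camera adjusted p = 0.77), and LDHA was at 961 ± 30 and 943 ± 36 CPM. Of 19 lactylation writers and erasers, 4 fell and 2 rose (4 and 3 adjusted over the list alone; camera adjusted p = 0.73). Without R-37 replicate 1 the fatty acid synthesis (adjusted p = 0.052), TCA cycle (0.059) and ribosomal lists (0.058) no longer passed camera, nor did the first 2 at a minimum count of 50 (0.051 and 0.060). With library size alone the TCA cycle had 1 gene up and 1 down, fatty acid synthesis 5 up and 6 down, cholesterol synthesis 2 up and 9 down, and ribosomal proteins 7 down. In that setting glycolysis (6 up, 2 down) and lactylation genes (6 up, 1 down) leaned upward. CS no longer passed there (adjusted p = 0.053) or in 2 FPKM settings (0.050 and 0.052).

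Several groups rose. Of 27 interferon-stimulated genes 12 rose and none fell (13 adjusted over the list alone; camera adjusted p = 0.000374, adjusted p = 0.034 with an estimated correlation). IFI35 went from 19.3 ± 3.4 to 30.9 ± 1.4 CPM and the helicase gene DDX60 from 11.3 ± 0.9 to 16.3 ± 1.2 CPM. Of 28 immediate early genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.0022, adjusted p = 0.41 with an estimated correlation), the risen ones including the phosphatase DUSP1 (log2 fold change 0.76) and the AP-1 subunit FOSL1 (0.55). Of 15 replication-dependent histone genes 8 rose (9 adjusted over the list alone; camera adjusted p = 0.000127, adjusted p = 0.056 with an estimated correlation), with H1-2 from 9.34 ± 0.85 to 18.1 ± 1.4 CPM and H2BC12 by 0.54. Histone values, here and below, are from polyA RNA and need not stand for all histone transcript. In the leukocyte marker list 3 of 5 tested genes rose, also 3 adjusted over the list alone (camera adjusted p = 0.0029, adjusted p = 0.059 with an estimated correlation). They were CD68, a lysosomal protein, from 72.3 ± 2.9 to 149 ± 14 CPM, CD79A from 2.41 ± 0.33 to 6.17 ± 0.81 CPM, and ITGAM by 0.84.

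Hepatocyte genes fell for 8 of 22 and rose for 3, as they did adjusted over the list alone (camera adjusted p = 0.042, adjusted p = 0.10 with an estimated correlation). The list no longer passed without R-37 replicate 1 (adjusted p = 0.069) or R-47 replicate 1 (0.057). ALB, which encodes albumin, fell from 13 ± 1.4 to 4.70 ± 0.70 CPM. Beyond the lists, the mucin gene MUC5B fell from 18.1 ± 1.1 to 4.97 ± 1.19 CPM and the imprinted RNA H19 from 971 ± 131 to 384 ± 35 CPM, while KCNK6 and APBB1IP rose by 1.32 and 1.31 on the log2 scale and ADPRHL1 from 2.41 ± 0.41 to 5.73 ± 0.84 CPM. The mesenchymal list had 8 genes lower and 4 higher of 21 (9 and 5 adjusted over the list alone; camera adjusted p = 0.26). The epithelial list had 2 lower and 6 higher of 15 (2 and 6 adjusted over the list alone; camera adjusted p = 0.17). FN1, which encodes fibronectin, fell by 0.78, whereas VIM was at 9.73 ± 0.84 and 9.48 ± 0.78 CPM and CDH1 at 18 ± 1.6 and 17 ± 0.7 CPM. With library size alone the mesenchymal balance turned to 4 lower and 5 higher. Leaving out R-37 replicate 1 or R-47 replicate 4 turned the sign of VIM, to 0.01 and 0.0075.

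The other lists did not pass camera after heating (adjusted p from 0.090 to 0.90): hypoxia (6 up, 1 down of 22), the ATF4 amino acid response (7 up, 4 down of 27), the mitochondrial unfolded protein response (1 up, 4 down of 15), p53 targets (5 up, 1 down of 23), DNA replication (0 up, 2 down of 34) and mitosis (3 up, 9 down of 34). The same held for fatty acid oxidation (2 up, 6 down of 20), respiratory complex I (0 up, 1 down of 38), NF-kB and inflammatory genes (6 up, 3 down of 24), autophagy and lysosome (7 up, 2 down of 28) and apoptosis (6 up, 3 down of 26). It also held for the markers of fibroblasts and stellate cells (1 up, 0 down of 5), endothelium (3 up, 2 down of 5) and cholangiocytes (2 up, 4 down of 12). The counts adjusted over the list alone differed for ATF4 (8 up, 4 down), p53 (6 up, 2 down), DNA replication (0 up, 1 down), mitosis (3 up, 10 down), fatty acid oxidation (2 up, 7 down), complex I (0 up, 0 down), autophagy (8 up, 3 down) and apoptosis (7 up, 4 down). With library size alone the balance turned for DNA replication (6 up, 1 down), mitosis (7 up, 2 down) and complex I (1 up, 0 down), and the mitochondrial unfolded protein response had 4 up and 4 down. Across genes, which are not independent replicates, the log2 fold change correlated with GC content at Spearman's rho 0.38 and with gene length at -0.22. With length and GC offsets, chosen after seeing the data, the immediate early list no longer passed (camera adjusted p = 0.16). By camera with the preset correlation, 8 of 41 chromosome arms, taken as gene sets, also passed after heating. With those offsets 0 arms passed, and with an estimated correlation in place of the preset 0 passed as well. The preset test thus also passed sets not chosen for a function.

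**Figure D2:**
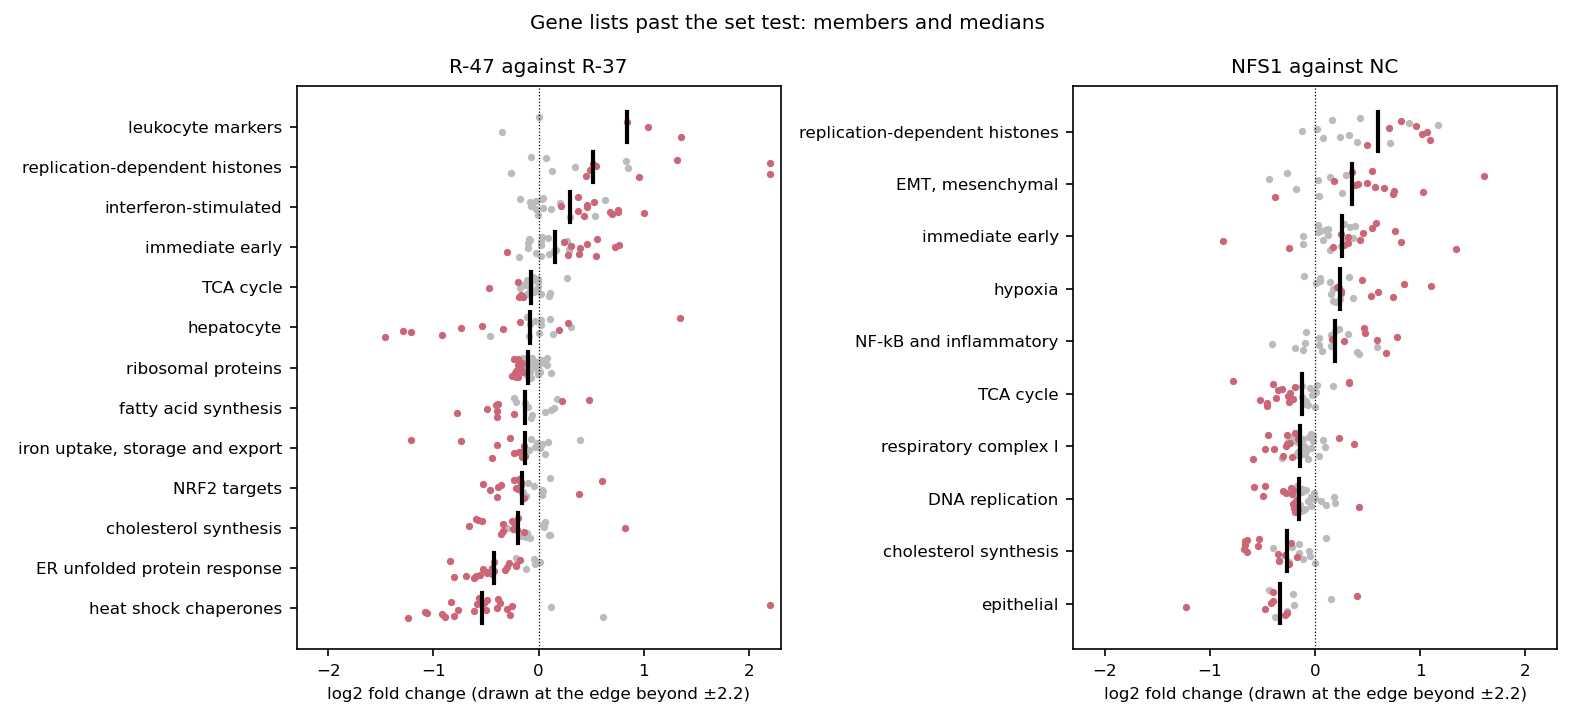
Log2 fold changes of the members of each gene list past the set test, for R-47 against R-37 (left) and NFS1 against NC (right). Red points passed the threshold, grey points did not, values beyond the axis are drawn at its edge, and black bars mark medians, such as -0.54 for heat shock chaperones after heating and 0.35 for the mesenchymal list in NFS1.

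The second comparison asked how the libraries labelled NFS1 knockdown differed from NC when both had been held at 47 °C. The gene named by the labels was itself hardly lower; the series title spells it NSF1, and the spelling of the sample labels, NFS1, was taken here. NFS1, on chromosome 20 from 35668052 to 35699352 in GRCh38 (20q, a protein-coding gene), stood at 78.0, 78.9, 77.3, 77.3 and 81.8 CPM in NC replicates 1 to 5 and at 76.8, 71.8, 70.7, 70.6 and 74.3 CPM in NFS1 replicates 1 to 5. The means were 78.7 ± 1.9 and 72.8 ± 2.7 CPM, a log2 fold change of -0.11 (SE 0.05, 95% interval -0.21 to -0.01), with every NFS1 library below every NC library. It did not pass the threshold (adjusted p = 0.11, edgeR), while an exact permutation test of the 10 log2 values, counting both directions, gave p = 0.0079, the smallest it can give. The interval excludes a loss of transcript above 13.5%, and the directions below refer to the libraries labelled NFS1 knockdown.

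Those libraries nonetheless differed widely from NC. By camera with its preset correlation, the lists of mesenchymal, hypoxia, NF-kB, immediate early and histone genes lay higher, and those of epithelial, cholesterol synthesis, DNA replication, TCA cycle and complex I genes lower. Of these 10 lists only cholesterol synthesis kept its call with an estimated correlation (adjusted p = 0.042), the others being at 0.081 to 0.59. TNC, an extracellular matrix protein, rose from 9.53 ± 0.52 to 29 ± 2.2 CPM (SD, n = 5 each) and the transcription factor SNAI2 from 14.4 ± 1.6 to 29.2 ± 2.8 CPM. Scaled over all 20 libraries, TNC averaged 28.9 CPM in R-47, the wild-type group at 47 °C of the first experiment, and 8.80 CPM in NC. SNAI2 went the other way, at 5.92 CPM in R-47 and 13.3 CPM in NC. The tight junction gene CLDN1 fell from 13.8 ± 1.8 to 5.90 ± 0.79 CPM. Of 15086 genes tested, 2364 were higher and 1881 lower by edgeR's quasi-likelihood test, 441 of them by more than 2-fold. Across genes, which are not independent replicates, the log2 fold change correlated with gene length at Spearman's rho 0.24 and with GC content at -0.23. With length and GC offsets, chosen after seeing the data, 2596 genes were higher and 3122 lower. Without NFS1 replicates 2 and 3, left out after their HSPA6 levels were seen, 1622 genes were higher and 1147 lower. Without NC replicate 1 and NFS1 replicate 4, also left out after seeing the data, 2955 were higher and 2604 lower.

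Of 21 mesenchymal genes, 12 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.000449, adjusted p = 0.13 with an estimated correlation). TNC had a log2 fold change of 1.60 (SE 0.08, adjusted p = 1.18e-08, edgeR), SNAI2 of 1.03 (SE 0.09), ZEB1 of 0.75 and FN1 of 0.74. VIM, which encodes the intermediate filament vimentin, was the member that fell, from 235 ± 12 to 180 ± 14 CPM. Of 14 epithelial genes, 7 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.0015, adjusted p = 0.35 with an estimated correlation). CLDN1 fell by 1.23 and the keratin gene KRT8 by 0.28. CDH1, at 4.31 ± 0.74 and 3.31 ± 0.66 CPM, did not pass the threshold (adjusted p = 0.098), though it did with all 20 libraries in one fit (0.020) and with length and GC offsets (0.046).

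Of 22 hypoxia genes 10 rose and none fell (13 adjusted over the list alone; camera adjusted p = 0.000166, adjusted p = 0.35 with an estimated correlation), with MXI1 from 13.4 ± 1.0 to 28.6 ± 2.7 CPM and NDRG1 from 343 ± 51 to 572 ± 68 CPM. Of 23 NF-kB and inflammatory genes 7 rose, also 7 adjusted over the list alone (camera adjusted p = 0.017, adjusted p = 0.13 with an estimated correlation), including ICAM1 by 0.48 and NFKB2 by 0.78. Of 30 immediate early genes 12 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.0036, adjusted p = 0.48 with an estimated correlation), including DUSP5 by 0.75 and EGR2 by 0.82. Of 18 histone genes 7 rose (9 adjusted over the list alone; camera adjusted p = 0.0062, adjusted p = 0.38 with an estimated correlation), H2BC5 by 1.02 and H2BC21 by 0.70. The histone list did not pass at a minimum count of 50 (adjusted p = 0.11), nor the immediate early list without NFS1 replicates 2 and 3 (adjusted p = 0.067).

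Of 24 cholesterol synthesis genes 13 fell and none rose (18 and none adjusted over the list alone), the 1 list that also passed with an estimated correlation (camera adjusted p = 3.1e-07, adjusted p = 0.042 with an estimated correlation). DHCR7, the last enzyme of the pathway, fell from 155 ± 6 to 97.6 ± 4.9 CPM and NSDHL from 54.4 ± 3.5 to 33.9 ± 3.2 CPM. Of 34 DNA replication genes 15 fell and 1 rose (16 and 1 adjusted over the list alone; camera adjusted p = 0.000428, adjusted p = 0.081 with an estimated correlation), POLA2 by 0.50 and CCNE1 by 0.58. Of 28 TCA cycle genes 13 fell and 2 rose (14 and 2 adjusted over the list alone; camera adjusted p = 0.000166, adjusted p = 0.35 with an estimated correlation), DLST by 0.37 and IDH3G by 0.52. Of 38 complex I genes 12 fell and 2 rose (15 and 2 adjusted over the list alone; camera adjusted p = 0.000449, adjusted p = 0.59 with an estimated correlation), NDUFV1 by 0.45 and NDUFB2 by 0.48.

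Genes of some chromosome arms also moved together. The median log2 fold change was 0.51 for the 427 tested genes of 10q and 0.39 for the 140 of 10p, and -0.44 for the 287 of Xq, -0.19 for the 563 of 11q and -0.18 for the 499 of 14q. With an estimated correlation camera gave adjusted p = 0.0014 for 10q, 0.089 for 10p, 0.000335 for Xq, 0.0055 for 11q and 0.00035 for 14q. It also gave 0.0021 for 1p and 0.0038 for 9p, where the medians were 0.07 and -0.07. MXI1, NFKB2, DUSP5 and EGR2 lie on 10q, NSDHL and IDH3G on Xq, DHCR7, POLA2, NDUFV1 and FTH1 on 11q and DLST on 14q. SFMBT2, on 10p, had the highest rise among the genes named by rule, from 0.323 ± 0.159 to 16.1 ± 2.3 CPM, and CSAG3 and ARMCX1, on Xq, fell by 1.47 and 1.23. EPHB2, on 1p, rose by 2.69. Away from these arms, the Wnt inhibitor NKD1 rose by 2.89, the vitamin D hydroxylase CYP24A1 by 2.21 and BACE2 from 6.42 ± 1.34 to 29.6 ± 2.2 CPM. There MYL9 and TFF1 fell by 1.70 and 1.37. The 5 highest rises named by rule were in genes that were also lower in NC than in R-47, a group of the other experiment. Scaled over all 20 libraries, SFMBT2 averaged 5.52 CPM in R-47 and 0.298 in NC, NKD1 2.81 and 1.26, and EPHB2 26.2 and 1.19. CYP24A1 averaged 138 and 5.19 CPM, and BACE2 36.7 and 5.93 CPM. The choice of these genes favours a low level in NC, and most tested genes differed between R-47 and NC. The 5 lowest changes named by rule were in turn higher in NC than in R-47, such as MYL9 at 6.79 and 3.83 CPM and CSAG3 at 7.26 and 0.922 CPM. These levels therefore cannot decide whether NC or NFS1 departed, which stays open. Without the genes of chromosome 10 and Xq, left out after seeing the data, 1961 genes rose and 1586 fell, and 11 lists passed camera, among them all 10 named above. That setting kept the genes of 11q, 14q, 1p and 9p, so it does not show that the lists are independent of chromosome position.

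**Figure D3:**
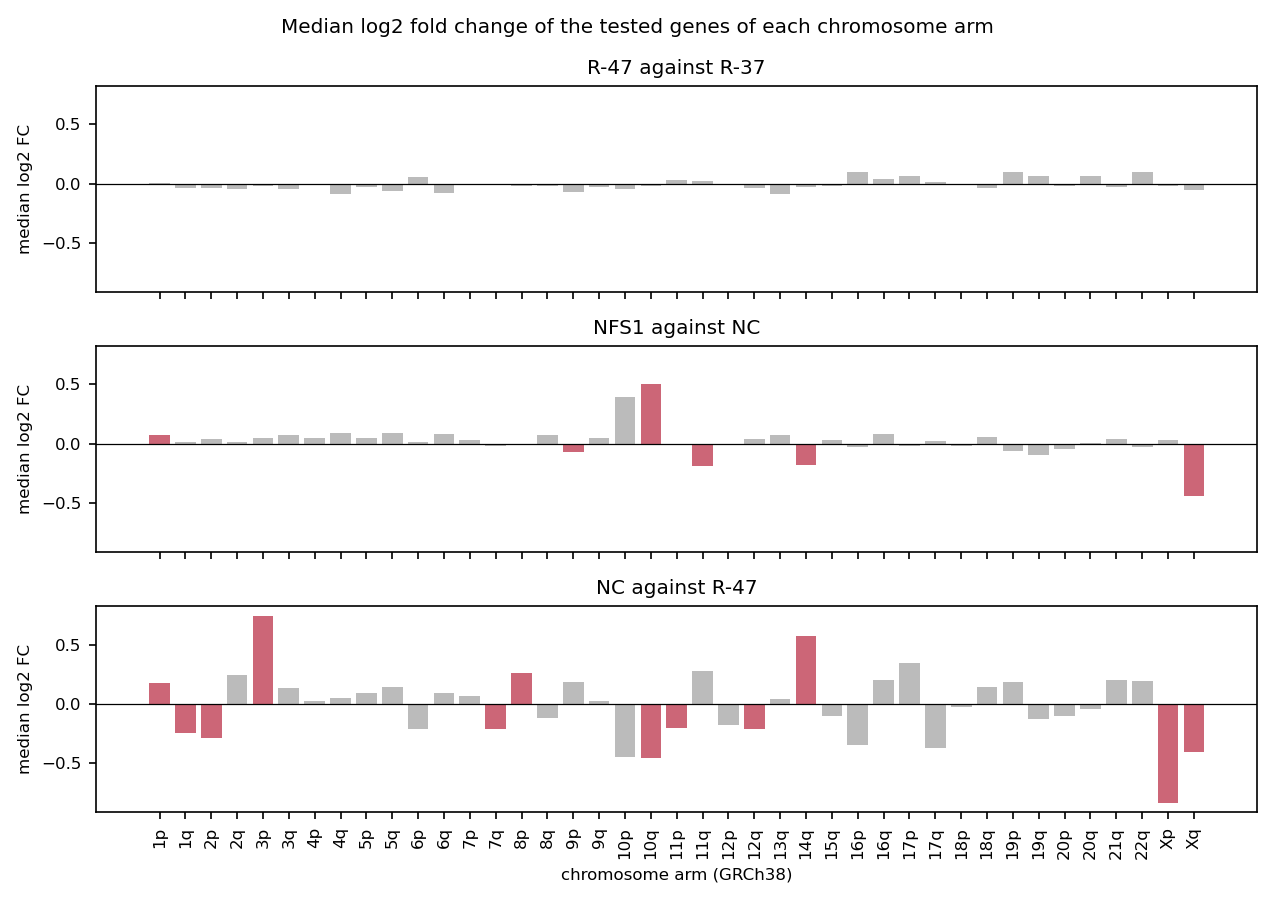
Median log2 fold change of the tested genes on each chromosome arm, for each of the 3 comparisons. Red bars passed camera with an estimated correlation: after heating the medians lay between -0.09 and 0.10 with no red bar, in NFS1 against NC 6 arms passed with 10q at 0.51 and Xq at -0.44, and in NC against R-47 12 arms passed.

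Ferritin was lower in the libraries labelled NFS1 knockdown. FTH1, which lies on 11q, an arm lower as a set, fell from 3759 ± 71 to 2692 ± 246 CPM (log2 fold change -0.48, SE 0.06, adjusted p = 3.98e-05, edgeR) and FTL by 0.33. Of 23 iron genes 6 fell and 2 rose, as adjusted over the list alone (camera adjusted p = 0.13), and of 27 iron-sulfur cluster assembly genes 6 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.14). Of 26 ferroptosis suppressors 7 fell and 5 rose (8 and 6 adjusted over the list alone; camera adjusted p = 0.38), and of 26 drivers 4 fell and 1 rose (3 and 1 adjusted over the list alone; camera adjusted p = 0.50). AIFM2 fell by 0.22 (SE 0.08, adjusted p = 0.046). SLC7A11 was at 153 ± 25 and 118 ± 27 CPM (log2 fold change -0.38, SE 0.14, adjusted p = 0.053), not past the threshold. GPX4 was at 422 ± 16 and 401 ± 39 CPM, TFRC at 805 ± 63 and 756 ± 81 CPM, and ACSL4 at 53.5 ± 6.6 and 48.2 ± 7.7 CPM, likewise not past the threshold. The call of AIFM2 ended with library size alone (adjusted p = 0.069), with the replicate block (0.074) and in the 3 FPKM settings (0.072 to 0.14). It also ended without NC replicate 2 (0.092), NC replicate 3 (0.088), NC replicate 4 (0.079), NC replicate 5 (0.087) or NFS1 replicate 2 (0.092). Without NFS1 replicate 4 SLC7A11 (adjusted p = 0.00032), ACSL4 (0.024) and TFRC (0.022) passed as lower. SLC7A11 also passed with DESeq2 (0.026), limma-voom (0.043), DESeq2 size factors (0.043), no filter (0.026), a minimum count of 50 (0.043), all 20 libraries in one fit (0.013) and length and GC offsets (4.12e-07). Of 25 glycolysis and lactate genes 4 fell and 5 rose (6 and 7 adjusted over the list alone; camera adjusted p = 0.62), with LDHA at 875 ± 69 and 950 ± 73 CPM. Of 19 lactylation writers and erasers 7 fell and 4 rose (7 and 6 adjusted over the list alone; camera adjusted p = 0.65), with 5 and 5 under library size alone.

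**Figure D4:**
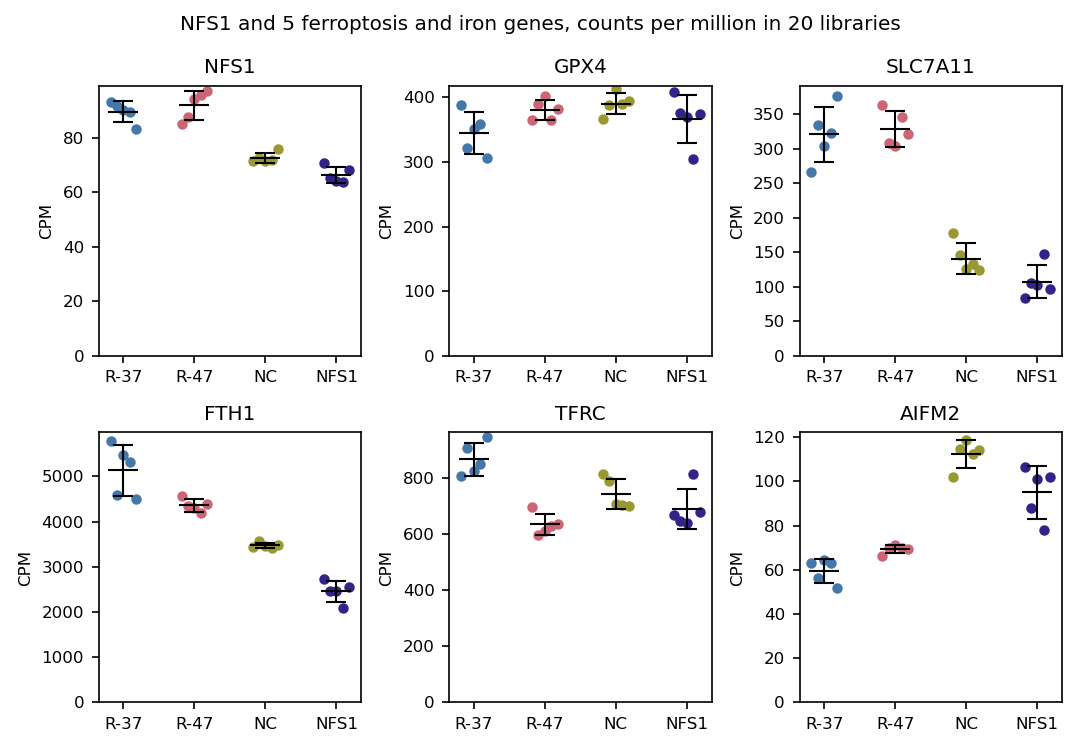
CPM of NFS1 and 5 ferroptosis and iron genes, 1 point per library with the mean and SD of each group (n = 5), scaled over all 20 libraries. FTH1 is lower in NFS1 than in NC, and NFS1 itself differs little between these groups.

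Heat shock chaperones did not pass as a list (5 up, 0 down of 24, as adjusted over the list alone; camera adjusted p = 0.14). The 5 that rose were HSPA6 by 2.82, HSPA1B by 2.26 (SE 0.60), HSPA1A by 1.90 (SE 0.58), BAG3 by 1.17 and DNAJB1 by 0.67 on the log2 scale. Scaled over all 20 libraries, HSPA1A ranged from 99.2 to 872 CPM within the NFS1 group. The call of HSPA1A ended when NFS1 replicate 2 (adjusted p = 0.075), NFS1 replicate 3 (0.067), NC replicate 2 (0.065) or NC replicate 3 (0.062) was left out. It also ended with the replicate block (0.079) and in the 3 FPKM settings (0.055 to 0.14). HSPA1B lost its call with the replicate block (0.065) and with FPKM and no filter (0.11). Without both NFS1 replicates 2 and 3, HSPA1A was at 0.68 (adjusted p = 0.38) and HSPA1B at 0.83 (adjusted p = 0.25). The remaining lists did not pass camera (adjusted p from 0.079 to 0.89): the ATF4 amino acid response (5 up, 3 down of 27), the endoplasmic reticulum (7 up, 4 down of 24) and mitochondrial (2 up, 4 down of 15) unfolded protein responses, NRF2 targets (8 up, 8 down of 25), p53 targets (4 up, 0 down of 23) and mitosis (4 up, 0 down of 34). Nor did fatty acid synthesis (3 up, 6 down of 19) and oxidation (2 up, 5 down of 20), interferon-stimulated genes (9 up, 2 down of 29), hepatocyte genes (2 up, 6 down of 19), ribosomal proteins (0 up, 5 down of 52), autophagy and lysosome (9 up, 4 down of 28) and apoptosis (5 up, 1 down of 27). The same held for the markers of fibroblasts and stellate cells (1 up, 0 down of 5), leukocytes (2 up, 0 down of 5), endothelium (0 up, 2 down of 6) and cholangiocytes (1 up, 3 down of 10). The counts adjusted over the list alone differed for ATF4 (7 up, 4 down), the endoplasmic reticulum (7 up, 5 down) and mitochondrial (2 up, 5 down) responses, NRF2 (8 up, 9 down), p53 (3 up, 0 down), mitosis (2 up, 0 down), interferon (10 up, 3 down), hepatocyte (4 up, 6 down), ribosomal (0 up, 1 down), autophagy (11 up, 6 down) and apoptosis genes (5 up, 0 down).

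The 2 comparisons share no libraries, and the next question was whether genes changed by heating moved in the libraries labelled NFS1 knockdown. Of the 1652 heat-raised genes tested in both, 307 were lower there, against 214 for independent lists, and 219 were higher, against 271. Of the 1839 heat-lowered genes, 455 were higher, against 302 for independent lists, and 215 were lower, against 238. The 2 comparisons followed GC content (Spearman's rho 0.38 and -0.23) and gene length (-0.22 and 0.24) in opposite directions, so the numbers for independent lists do not stand for no relation, and the excess is not read as a shared effect. As sets, heat-raised genes did not pass camera with an estimated correlation (p = 0.52, direction down), nor did heat-lowered genes (p = 0.55, direction up), while with a preset correlation of 0.01 both passed (p = 0.0145 and 0.0105). Across 13777 genes, which are not independent replicates, the 2 log2 fold changes correlated at Pearson's r -0.09 and Spearman's rho -0.17. The genes named for opposite changes were TM4SF5, RAB37, GCKR and CYP2C18, raised by heating by 0.91, 0.89, 0.77 and 0.74 and lower in NFS1 by 0.84, 0.79, 0.77 and 1.15 on the log2 scale. In reverse, the collagen gene COL6A3 fell by 0.98 after heating and was higher by 1.60 in NFS1, and ETV1 fell by 1.02 and was higher by 0.81, beside HSPA1A and HSPA1B.

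NC and R-47 carry the same labels, wild-type at 47 °C, but belong to different experiments, so their difference measures how far the experiments lie apart. Of 15080 genes tested, 6043 were higher and 5978 lower in NC (edgeR), 4106 of them by more than 2-fold. VWA3A went from 0.0614 ± 0.0591 CPM in R-47 to 15.2 ± 1.2 CPM in NC, HCP5B from 0.0456 ± 0.0260 to 9.92 ± 0.41 CPM and MLLT3 from 0.0985 ± 0.1034 to 12 ± 1.1 CPM. B4GALNT1, at 16.2 ± 1.1 CPM in R-47, had no count in any NC library and was at least 1044-fold lower against a floor of 3 counts over the group. COX7B2 and ADAM12, at 13.7 ± 0.6 and 13.1 ± 1.6 CPM in R-47, likewise had no count in NC and were at least 878-fold and 843-fold lower. Of 34 lists, 7 passed camera. DNA replication (23 up, 5 down of 34), complex I (25 up, 5 down of 38) and ribosomal protein genes (33 up, 11 down of 52) were higher in NC, with adjusted p = 0.34, 0.65 and 0.76 with an estimated correlation. Mitosis (2 up, 29 down of 34), the ATF4 amino acid response (3 up, 22 down of 27), the endoplasmic reticulum unfolded protein response (3 up, 17 down of 24) and NRF2 targets (5 up, 17 down of 25) were lower, with adjusted p = 0.41 for mitosis and 0.34 for the others with an estimated correlation. All 7 counts were the same adjusted over the list alone, and the 7 balances kept their direction with library size alone. Batch, any control construct, selection of cells and another line or subline in 1 experiment cannot be told apart here. Scaled by library size alone, which moved the median of all genes to 0.19 on the log2 scale, 7465 genes were higher and 4740 lower.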

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

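The tests of the difference between NC and R-47, of the NFS1 level and of extra copies of chromosome 10 were chosen after their results had been seen, and those of other splits, of length and GC bias on 10q and of single libraries on 10q before. Single libraries stood far from the rest of their group in 9 of 213 groups of values tested, where chance gives about 5%. R-37 replicate 4 had 18105 genes detected, against 18454 to 18544 in the others of its group. INSIG1 was at 30.3 CPM in R-47 replicate 1, against 23.3 to 24.4 CPM. In NC, H2BC21 was at 5.80 CPM in replicate 5 (others 4.64 to 4.98 CPM), MXI1 at 15.1 CPM in replicate 4 (12.6 to 13.2 CPM) and NDUFB2 at 57.1 CPM in replicate 1 (68.9 to 73.4 CPM). NFS1 replicate 4 also stood apart over all genes, with a mean chi-square per gene of 57.3 to 72.5 against the other NFS1 libraries, which gave 3.53 to 17.5 among themselves. In R-37, replicate 5 gave 54.6 and 41.4 against replicates 1 and 3, which gave 4.69 between them, and replicate 2 gave 31.9 and 22.4. NFS1 replicate 4 held 3 of the 9: NFKB2 at 60.6 CPM (others 80.3 to 88.3 CPM), SFMBT2 at 20.1 CPM (14.8 to 15.4 CPM) and TFRC at 899 CPM (705 to 739 CPM). VWA3A was at 0.165 CPM in R-47 replicate 1, against 0.0274 to 0.0565 CPM.

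NC and R-47 carry the same labels yet differed in 12021 genes, and the highest count among 99 other splits of these libraries was 0, so chance can be excluded for that count among these libraries, which may be technical repeats. Length and GC bias is argued against as the whole cause, since 11313 genes were called both without and with length and GC offsets. After those offsets 27 of 41 chromosome arms passed camera with an estimated correlation, and 12 passed without them. The correlation was estimated within groups of libraries that may be technical repeats, so genes of an arm that move together for other reasons can also pass. The arms therefore do not decide on a batch difference with equal chromosome content. Different chromosome content of the cells remains a candidate explanation, with a largest arm shift of 0.82 on the log2 scale after the offsets, at 3p. Batch, construct, selection of cells and another line or subline in 1 experiment go with the experiment and cannot be told apart, so whether both used the same MHCC-97H cells is in doubt.

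In the libraries labelled NFS1 knockdown, genes of chromosome 10 were higher and genes of Xq lower than in NC. The splits tested the count of changed genes and not this pattern: 4245 stood against 0 at most in 99 others, so chance can be excluded for that count among these libraries, which may be technical repeats. Length and GC bias is argued against, since the 10q median was 0.46 with offsets and 0.51 without, and so is a single deviating library, since the lowest 10q median with any library left out was 0.48. Of 426 genes of chromosome 10 with an average log2 CPM of at least 2, 91.3% lay above 0, with a median ratio of 1.40. A different copy number of that chromosome in the 2 groups is a hypothesis, and which group departed is not known. NC itself lay below R-47 there, with a median log2 fold change of -0.45 for both 10q and 10p. Camera with an estimated correlation gave adjusted p = 0.032 and 0.27 for these arms. More copies in the cells labelled NFS1 and fewer in NC are thus not told apart. An effect of the knockdown on these arms stays open and untested, since no DNA measurement was used here.

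NFS1 transcript was lower by only 7.39% in the libraries labelled as its knockdown, although 4245 genes differed from NC. A swap of some libraries between the 2 groups is argued against, since 0 of the 10 libraries correlated better with the other group than with its own, which says nothing about an exchange of all labels. Such an exchange hiding a loss of 50% would need NFS1 to be doubled in the libraries labelled NFS1, and is argued against by the upper end of the 95% interval, -0.0130 on the log2 scale. Low depth is argued against, since every library had at least 2515 NFS1 counts and the 95% interval reached a loss of 13.5% at most, short of 50%. What stays open and untested is a loss at the protein level, a loss that had ended by the time of sampling, and other causes of the difference between the groups.

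Of the 126 possible splits of each pair of groups 100 were drawn. The count of 3604 genes after heating was above the highest of 99 other splits, which called 829. Chance can thus be excluded at a share of 1 in 100, for that count among these libraries, which may be technical repeats. For the 13 lists after heating, 2 of 100 splits, the real one among them, gave as many, and since the other gave 14, chance can be excluded only at that share. For the 10 lists in the knockdown comparison, 20 of 100 splits gave as many, up to 15, so chance cannot be excluded for that number. The splits that gave 829 genes, 14 lists and 15 lists each differed from the real one by an exchange of 1 library of each group. Such splits keep much of the real contrast, so their counts are not those of unrelated groups.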

How the results depend on the processing

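Settings that leave out genes of chromosome 10 and Xq or pairs of libraries, or that add length and GC offsets, were chosen after seeing the data. Counts of changed genes stayed within 1.5 times except in 1 setting, and leaving out 1 library at a time gave 2668 to 4334 genes after heating, 3376 to 5137 in the knockdown comparison and 11860 to 12201 in NC against R-47. Without R-37 replicates 2 and 5, which stood furthest from replicates 1 and 3, 3453 genes were called after heating. Without NFS1 replicates 2 and 3, which had the highest HSPA6 levels, 2769 genes were called, and without NC replicate 1 and NFS1 replicate 4, also 8 libraries, 5559. The number of lists moved from 13 to 6 after heating and from 10 to 1 in the knockdown comparison with an estimated correlation, and to 23 and 17 with fry, which asks another question and ended the calls of ribosomal proteins after heating (adjusted p = 0.15) and complex I in the knockdown (0.088). It was 9 to 14 and 10 to 12 with 1 library left out. NFS1 passed as lower with DESeq2 (log2 fold change -0.12, adjusted p = 0.043) and with all 20 libraries in one fit (-0.13, adjusted p = 0.049), the cause was not tested, and it was -0.14 to -0.10 with 1 library left out. In the other settings its adjusted p was 0.061 to 0.32. Heat-raised and heat-lowered genes passed in the knockdown with a preset correlation (p = 0.0145 and 0.0105). The 44 heat-lowered genes over 2-fold pointed down with an estimated correlation (p = 0.44), and the cause was not tested. With 1 library left out the p-values were 0.42 to 0.70 and 0.46 to 0.74.

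Nothing says that the replicate numbers pair the samples, and the values gave no clear sign of it. Same-number correlations were -0.11 to 0.11 for heating and -0.23 to 0.08 for the knockdown, with 1 and 0 of 5 numbers correlating best with their own. For NC against R-47 they were -0.0084 to 0.15, with 2 of 5. Low correlations cannot exclude a pairing. With the replicate block 2928, 3068 and 12104 genes were called in the 3 comparisons, 13 and 10 lists passed, and NFS1 was at -0.11 (adjusted p = 0.22). The block ended the calls of HSPA1A (adjusted p = 0.079), HSPA1B (0.065) and AIFM2 (0.074) in the knockdown.

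After heating, genes not past the threshold changed sign: LDHA (0.0486 with library size alone, 0.0483, 0.0484 and 0.0483 in the 3 FPKM settings, 0.0215 with offsets), VIM (0.0370 with library size alone, and 0.0308, 0.0369 and 0.0308 with FPKM), GPX4 (-0.0422 with offsets), ACSL4 (0.0118 with offsets and 0.0332 without R-37 replicates 2 and 5) and CDH1 (0.0135 without those libraries). With 1 library left out, VIM ranged from -0.0721 to 0.0122 and SLC7A11 from -0.0175 to 0.112. In the knockdown GPX4 was at 0.0557 with offsets. The causes were not tested. Among the other values of named genes under planned settings, 9 calls after heating and 20 in the knockdown were lost and 5 and 10 gained, and no gene of NC against R-47 changed its call. The share of rises moved from 47.6% after heating to 74.6% with library size alone and 75.1% with log2(FPKM + 1), from 50.3% to 61.2% in NC against R-47, and from 55.7% to 45.4% with offsets in the knockdown. In simulated counts small changes were often missed. The smallest simulated fold change was recovered in 54% of genes for heating and 28% for the knockdown. Far fewer genes were changed in the simulation than were called in the data, which made the adjusted threshold stricter there. How often small changes were missed in the data was therefore not measured.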

Other observations

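The genes described here were chosen after their values had been seen. Heat-inducible HSP70 transcripts varied more within the second experiment than within the first. HSPA6, an HSP70 gene with a low basal level, lay at 0.328 to 1.49 CPM in the R-37 and R-47 libraries, at 5.41 to 39.0 CPM in NC and at 22.3 to 251 CPM in NFS1 (scaled over all 20 libraries). Within NC, HSPA6 rose with each replicate number, and so did HSPA1A, from 42.5 CPM in replicate 1 to 244 CPM in replicate 5. The NFS1 libraries did not follow that order, and the cause was not tested. NFS1 replicates 2 and 3 had 251 and 246 CPM of HSPA6, and 872 and 839 CPM of HSPA1A, against 99.2 to 297 CPM of HSPA1A in the others. DNAJB1, a co-chaperone, was at 275 and 284 CPM in these 2 libraries and at 113 to 144 CPM in the other 3. CRYAB, by contrast, was at 43.0 to 62.8 CPM in NC and 45.3 to 72.3 CPM in NFS1, above the 13.8 to 18.9 CPM of R-47.

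The experiments also differed widely in single surface and keratin genes, though no list of such genes was tested and most tested genes differed between R-47 and NC. CD81, a tetraspanin, was at 67.8 ± 3.6 CPM in R-47 and 0.0311 ± 0.0336 CPM in NC, and KRT19, an epithelial keratin, at 425 ± 19 and 0.802 ± 0.132 CPM. VIM went the other way, from 10.4 ± 0.9 to 219 ± 10 CPM. KRT8, another keratin gene, differed less, at 4535 CPM in R-47 and 3213 CPM in NC (scaled over all 20 libraries). In all, 8 genes lay at 10 CPM or more in every R-37 and R-47 library and under 0.1 CPM in every NC and NFS1 library: ADAM12, ADGRF1, B4GALNT1, CD81, CDH6, COX7B2, UPK1B and VCAM1. The reverse was seen for 0 genes at these cutoffs. VWA3A came near it, at 13.6 to 18.5 CPM in the NC and NFS1 libraries and at most 0.169 CPM in R-37 and R-47.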
